A study of Mus musculus with 11 samples.

How the data were processed

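Messenger RNA was measured by bulk RNA sequencing in epithelial cells taken from fetal mouse lung at E17.5. Per the labels' protocols, lungs were dissociated with enzymes, red cells were lysed, cells carrying the epithelial surface protein EpCAM were held back on magnetic microbeads, and poly(A) RNA was sequenced. There were 6 Control libraries and 5 libraries from mice in which floxed alleles of Prdm16 and of Prdm3 (listed under its present symbol, Mecom) were recombined by a Cre inserted at the Shh gene, which is active in the lung epithelium. The labels give each library a genotype and a number. They do not say whether libraries came from separate animals, so the p-values measure the spread between these 11 libraries, part of which may be technical. They give no litter, sex or sequencing batch either.

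The authors deposited a single table of counts per gene, whole numbers under gene symbols, with 24421 rows. The submitters' processing notes name FastQC, Trim Galore 0.4.2, Bowtie2 2.4.2, SAMtools 1.10.0, Picard 2.18.22, HTSeq 2.0 and DESeq2, and the mouse build mm10, without saying what each did. The annotation, the strand setting, the handling of duplicate reads and the handling of reads that match several genes are not given in the sources used here. Genes that overlap on opposite strands can therefore not be told apart. Spreadsheet software had turned the symbols of 27 rows into dates and 2 symbols stood on more than 1 row; these rows stayed in the totals and are not named. Symbols were matched to GENCODE release M21, which is on the same build: 23311 matched directly and 667 through an older name, together 98.2% of rows. Coordinates are from that annotation, counted from 1.

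Totals ran from 6065906 to 7869787 counts per library. Genes with too few counts were removed with edgeR's filterByExpr, which left 13916. Library sizes were scaled by TMM (trimmed mean of M values), and the genotype effect was tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test with robust moderation, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. A log2 fold change is knockout over Control, and its standard error is the unshrunk coefficient divided by the square root of F. CPM, counts scaled to a common library size, uses the TMM-scaled library sizes and is given as mean ± SD over 6 Control and 5 knockout libraries. Intervals on ratios of summed counts cover counting error only.

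Before the data were examined, 32 gene lists of textbook markers and pathways were fixed. Apart from the list of Y-linked transcripts, the 31 lists were tested with limma's camera (3.58.1), which asks whether a list's genes rank apart from the other genes, with a preset correlation between genes of 0.01 and adjustment over the lists. The rule for named genes was fixed at the same time. It takes Prdm16, Mecom, Shh, Nkx2-1 and Epcam in any case. It adds the 10 largest and the 10 smallest log2 fold changes among genes past the threshold with a mean of at least 5 CPM in the higher group and CPM ranges that do not overlap, and the 5 genes in each direction with the smallest p; predicted genes and unnamed clones are left out of both. From each list it takes up to 4 members past the threshold by adjusted p and up to 2 of the most abundant that did not pass, some of which are left out. Sftpc, Sftpb, Sftpa1, Sftpd, Abca3, Lamp3, Ager, Rtkn2, Calca, Chga, Srebf1 and Piezo2 are outside the rule: these 12 were chosen after their values were seen, Piezo2 as the member of its list that fell and the others as widely used markers. Transcripts given only for their count levels among the other observations were chosen in the same way.

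The steps were tested on counts simulated from the real means and library sizes of the knockout and Control comparison. After the filter on low counts, 13820 simulated genes were tested. At each fold size 50 genes were changed, and a list of 25 further genes was moved together, 225 changed genes in all. edgeR called 22% of the genes changed 1.25-fold, 60% of those changed 1.5-fold, 80% of those changed 2-fold and 100% of those changed 4-fold, and 6.13% of its calls fell on unchanged genes. The pass limit for the 2-fold class was loosened after that share was seen. Estimated log2 fold changes followed the simulated ones with a slope of 0.998.

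Alternatives fixed in advance were DESeq2 size factors, library size only, upper-quartile factors, no filter on low counts, at least 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom with and without library weights, no robust moderation, the replicate number as a block, a Y-linked or a mesenchymal covariate, each library left out in turn, a threshold of 0.01, camera with an estimated correlation, and fry. The choices made after seeing the data were leaving out Control libraries 5 and 6, and fitting separately the libraries with low and with high Y-linked transcripts, divided at a mean of 3 log2 CPM.

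Transcripts of the 153 named genes were searched for 50-base words that also occur in transcripts of other genes. At least 25% of the words were shared for 9 of them: Nrarp, Krt6a, Ugt1a6a, Timp3, Phlda1, Pcna, Prss32, Idi2 and Etv5. Counts of these genes are uncertain, since reads may have been split with, or lost to, a copy or an overlapping gene.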

Results

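The series compared gene expression in EpCAM-selected lung epithelium of E17.5 mouse embryos carrying a conditional knockout of Prdm16 and Prdm3 in Shh-Cre expressing cells with that of Control mice. Both genes encode zinc-finger proteins of the PR domain family, and the series title sets them in alveolar differentiation driven by the transcription factor NKX2-1. There were 6 Control libraries, with 6065906, 7668915, 6659510, 6116186, 7157118 and 7869787 counts, and 5 knockout libraries, with 7286156, 7371673, 7488494, 7563280 and 7652477 counts. The first principal component held 68.1% of the variance and separated the groups. Correlations of log2 CPM were 0.957 to 0.990 within groups and 0.910 to 0.935 between them, and no library correlated best with a library of the other group.

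The targeted genes were read first. Prdm16 lies on chromosome 4 from 154316125 to 154636873 (mm10, minus strand). It was counted at 227, 208, 226, 173, 190 and 188 CPM in Control libraries 1 to 6 and at 167, 169, 147, 181 and 165 CPM in knockout libraries 1 to 5. Its mean was 202 ± 21.9 CPM in Control (SD, n = 6) and 166 ± 12.2 CPM in the knockout (SD, n = 5). The log2 fold change was -0.28 (SE 0.079; edgeR quasi-likelihood test, adjusted p = 0.00905), and the ranges overlapped. Mecom lies on chromosome 3 from 29951296 to 30548008 (minus strand). It was counted at 214, 233, 226, 206, 213 and 219 CPM in Control libraries and at 321, 349, 325, 352 and 354 CPM in knockout libraries. Mecom was therefore higher in the knockout, from 219 ± 9.99 to 340 ± 16.0 CPM, a log2 fold change of 0.64 (SE 0.057; edgeR, adjusted p = 3.26e-07). The counts cover whole genes, and the labels do not name the deleted exons. Any transcripts lacking those exons would still be counted, so these values are a weak check of the deletion. The Prdm16 log2 fold change was not called with library-size scaling alone (-0.18; edgeR, adjusted p = 0.0576) or with the mesenchymal covariate (-0.20; edgeR, adjusted p = 0.236); over the alternatives its adjusted p ran from 0.00115 to 0.62.

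Shh, which carries the Cre insertion (chromosome 5, 28456815 to 28467256), fell from 319 ± 35.1 to 248 ± 17.47 CPM (log2 fold change -0.36; edgeR, adjusted p = 0.00212). Nkx2-1 (chromosome 12, 56531958 to 56536908) fell from 1335 ± 109 to 1098 ± 91.0 CPM (log2 fold change -0.28; edgeR, adjusted p = 0.010). The Nkx2-1 log2 fold change was not called with library-size scaling alone (-0.18; edgeR, adjusted p = 0.10) or with the mesenchymal covariate (-0.29; edgeR, adjusted p = 0.0815); over the alternatives its adjusted p ran from 0.000905 to 0.725. Among the named genes called here and below, the CPM ranges of the groups overlapped for Prdm16, Shh, Nkx2-1, Pdpn, Ccno, Mcidas, Ccdc113 and Rrm2, and for no other. Epcam, the protein used for selection, had a log2 fold change of 0.05 (edgeR, adjusted p = 0.601), at 252 ± 25.3 and 261 ± 10.8 CPM.

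**Figure D1:**
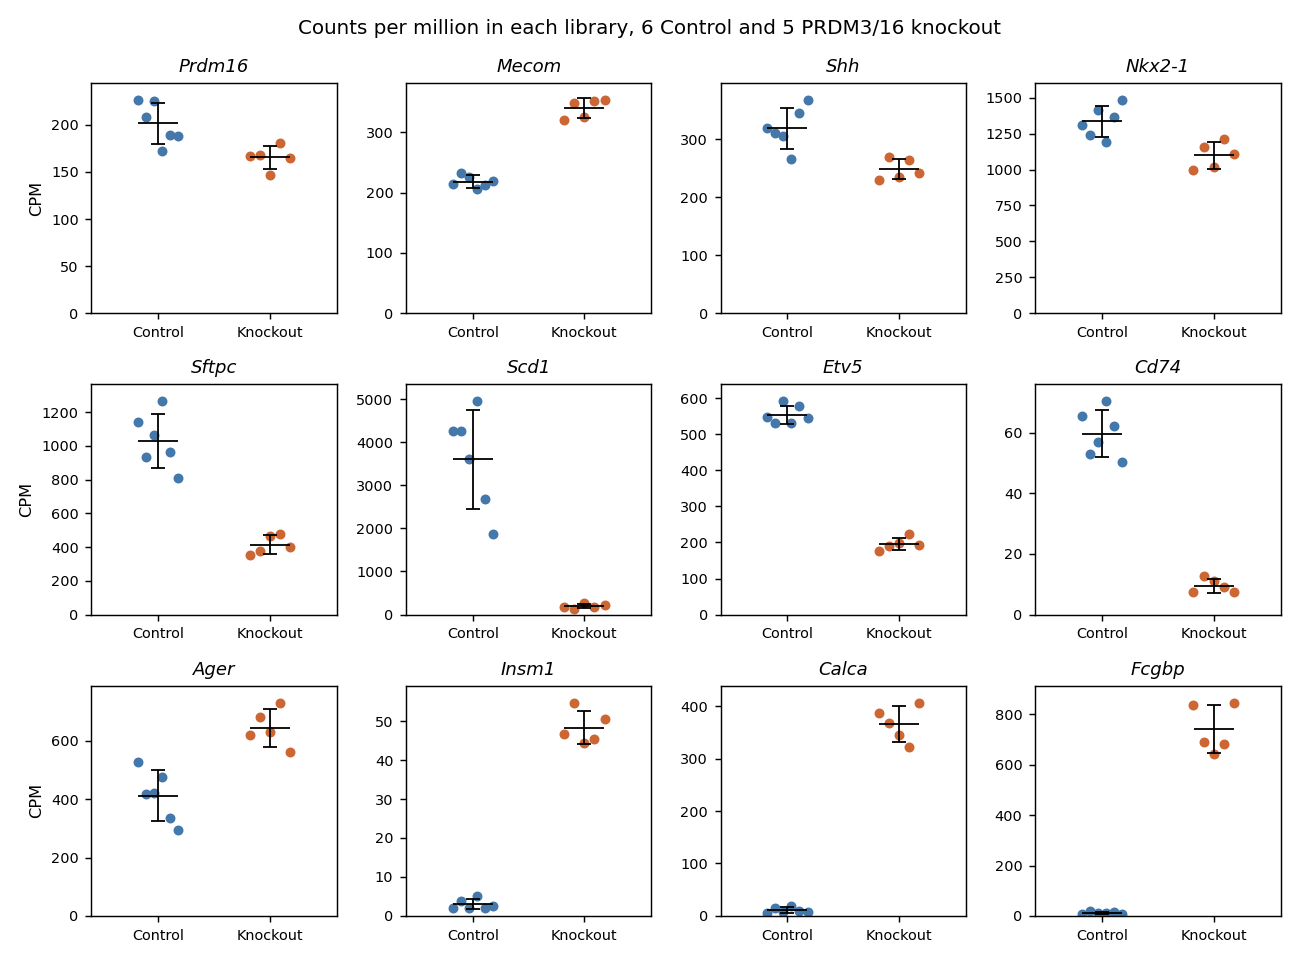
CPM on the vertical axis for 12 genes in each of the 6 Control and 5 knockout libraries; points are libraries, long bars are means and error bars are SD. Prdm16 ranges overlap, Mecom is higher in each knockout library (321 to 354 CPM) than in any Control library (206 to 233 CPM), and Sftpc, Scd1, Etv5 and Cd74 are lower in each knockout library.

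Genes across the whole profile differed between the groups. Of 13916 genes, 2936 were higher and 3037 lower in the knockout by edgeR's quasi-likelihood test, 42.9% in all, and 1589 changed at least 2-fold, 963 higher and 626 lower. The 2 groups' CPM did not overlap for 3962 genes, 28.5% of those tested, where chance gives 0.433%. Among genes that rose, Fcgbp, which encodes a mucus-associated protein (chromosome 7, 28071236 to 28120862), went from 11.9 ± 3.61 to 741 ± 95.1 CPM (log2 fold change 5.95, SE 0.17). The keratin gene Krt6a, which shares sequence with other genes, went from 0.369 ± 0.298 to 65.2 ± 18.4 CPM (7.48), the guanylin gene Guca2a from 0.449 ± 0.303 to 26.6 ± 3.73 CPM (5.84), and the mucin glycosyltransferase gene Gcnt3 from 0.286 ± 0.214 to 17.4 ± 2.67 CPM (5.90). Among genes that fell, Scd1, which encodes a fatty acid desaturase (chromosome 19, 44394455 to 44407879), went from 3608 ± 1145 to 194 ± 46.5 CPM (-4.22, SE 0.27) and Retnla from 145 ± 44.2 to 5.17 ± 1.92 CPM (-4.80).

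Some of the largest ratios rest on few Control counts. Lce6a had 3 counts over the 6 Control libraries and 717 over the knockout libraries, a ratio of 266 (95% counting interval 90.6 to 1291). For Car10 the counts were 1 and 219 (ratio 243, interval 43.2 to 9660), for Idi2 2 and 215 (120, interval 32.7 to 993) and for Pla2g2f 3 and 216 (80.0, interval 27.0 to 391). St18 and Prss32 complete the 10 largest increases among called genes with a mean of at least 5 CPM in the higher group and ranges that did not overlap, with log2 fold changes of 5.75 and 5.57. St18 had 7 Control counts (ratio 63.7, interval 30.6 to 159) and Prss32 had 6 (56.7, interval 25.8 to 156). The other large decreases were those of Pon1 (-5.22), Cytl1 (-5.09), Tinag (-4.36), Tmem132d (-4.17), Ugt1a6a (-4.17), Ism2 (-4.12), Ros1 (-4.10) and Sgpp2 (-4.04). Pon1 had 213 Control and 5 knockout counts, a ratio of Control over knockout of 38.3 (95% counting interval 16.2 to 119).

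By p-value, the genes leading the increases were Nptx1 (log2 fold change 3.84), Slc8a3 (5.51), Upk3a (3.93), Sh3tc2 (3.43) and Pcsk1 (3.70). Leading the decreases were Rbpjl (-3.31), Tinag, Egfl6 (-2.45), Matn4 (-2.78) and Rprm (-2.67). The smallest adjusted p by edgeR was 4.23e-13, for Nptx1 and Rbpjl. With library-size scaling alone the median log2 fold change of all genes moved from 0.0023 to 0.11, and the calls became 3992 higher and 2095 lower, 65.6% higher against 49.2%.

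**Figure D2:**
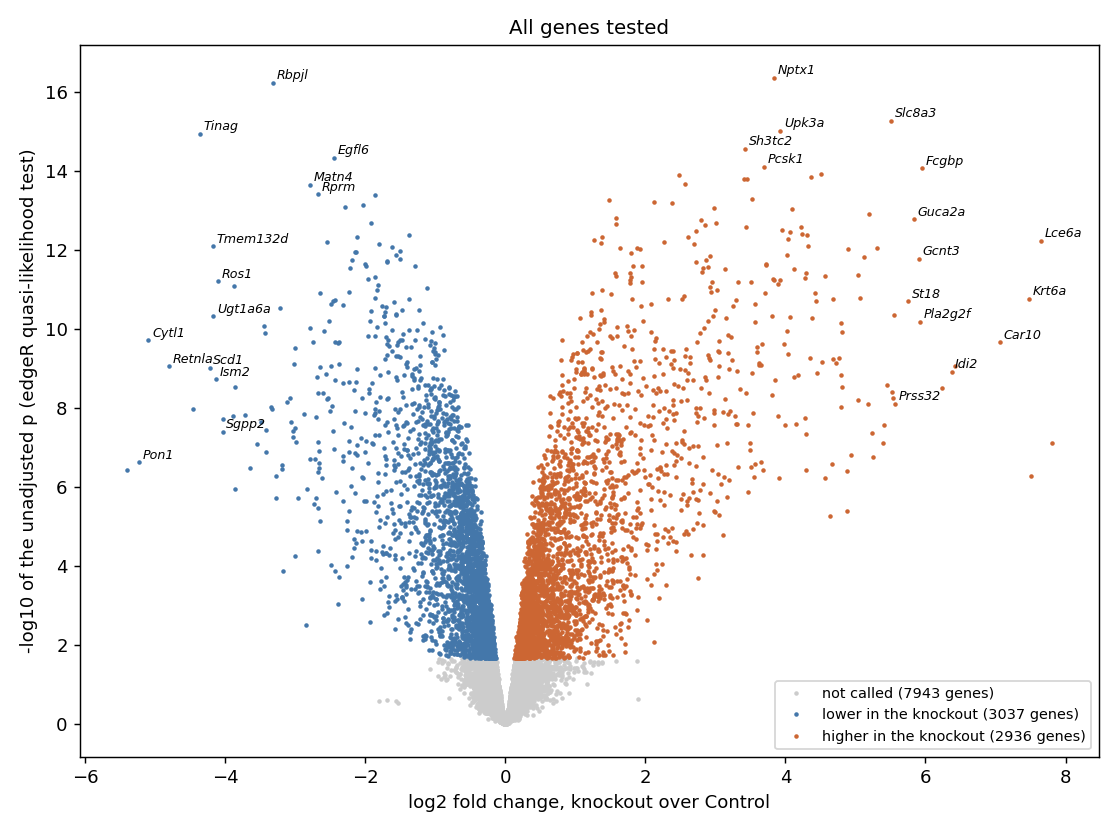
Log2 fold change (horizontal) against -log10 of the unadjusted p of edgeR's quasi-likelihood test (vertical) for 13916 genes; colours mark the 2936 genes higher, the 3037 lower and the rest. Labels mark the genes with the largest changes or smallest p by the fixed rule, such as Fcgbp (5.95) and Pon1 (-5.22).

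Samples also differed in ways the genotype labels do not record. Y-linked transcripts were high in Control libraries 1, 3, 4 and 5 and in knockout library 4 (mean log2 CPM 5.30 to 5.43) and low in the other 6 (-2.47 to 0.11). Among low-Y libraries alone, 2 Control and 4 knockout, 1932 genes were higher and 1821 lower by edgeR. Among high-Y libraries, 4 Control and 1 knockout, assumed to vary like the others, the counts were 869 and 933. Within these sets, Mecom had log2 fold changes of 0.57 and 0.71, and Prdm16 of -0.30 and -0.18, the last not called (edgeR, adjusted p = 0.62). Mean log2 CPM of proliferation genes was 4.75 and 5.13 in Control libraries 5 and 6, against 3.55 to 4.10 in the other Control libraries. Without these 2 libraries, 3183 genes were higher and 3345 lower.

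Markers of alveolar type 2 cells, which make surfactant, were lower in the knockout. Of 30 list members, 29 fell (29 adjusted over the list alone) and 0 rose; Lyz2 alone did not pass, at 421 CPM in both groups. The median log2 fold change was -1.69 (camera, adjusted p = 3.47e-37), with adjusted p = 0.104 with an estimated correlation. The median was -1.55 among low-Y and -1.56 among high-Y libraries, and -1.66 with the mesenchymal covariate. Surfactant protein genes fell: Sftpc from 1030 ± 163 to 415 ± 55.7 CPM (log2 fold change -1.31, SE 0.12), and Sftpb (-1.70), Sftpa1 (-1.13) and Sftpd (-3.33) with it. Lamp3 and Abca3, of the lamellar bodies that store surfactant, had log2 fold changes of -2.79 and -1.40. The FGF-responsive transcription factor Etv5 fell from 554 ± 25.4 to 196 ± 17.2 CPM (-1.50, SE 0.070; chromosome 16, 22381309 to 22439719; it shares sequence with other genes). The protease gene Ctsh (-1.76) and Nkd1 (-1.74), a Wnt antagonist, fell as well.

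Alveolar type 1 markers, of the flat cells of gas exchange, went both ways: 7 of 30 rose, 4 fell and 19 did not pass (7 and 4 adjusted over the list alone). The list median was 0.14 (camera, adjusted p = 0.626), and -0.0039 without Control libraries 5 and 6. Ager rose from 413 ± 86.3 to 645 ± 64.4 CPM (0.65, SE 0.13), and Rtkn2 (1.01), Agrn (0.66) and Scnn1g (0.73) rose, while Cldn18 (-0.67) and Icam1 (-0.59) fell. Hopx had a log2 fold change of 0.11 and Aqp5 of 0.41, neither called, and Timp3 (-0.0048) and Gprc5a (0.014) did not pass. Mean log2 CPM of the list was 8.6 and 8.42 in Control libraries 5 and 6 and 8.81 to 9.02 in the other 9.

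Lipid synthesis genes fell with the surfactant genes. In the fatty acid and phospholipid list, which shares Scd1 and Lpcat1 with the type 2 list, 20 of 27 members fell and 2 rose (21 and 2 adjusted over the list alone). The median was -0.69 (camera, adjusted p = 2.77e-09; adjusted p = 0.239 with an estimated correlation). Fatty acid synthase, Fasn, fell from 1811 ± 291 to 570 ± 34.1 CPM (-1.67, SE 0.11). Lpcat1 (-1.68), which makes the main surfactant lipid, and the regulator Srebf1 (-0.84) fell as well. The elongase Elovl6 rose, from 4.00 ± 1.18 to 19.3 ± 2.24 CPM (2.25). In cholesterol synthesis 9 of 23 members fell and 3 rose (10 and 3 adjusted over the list alone; camera, adjusted p = 0.129), among them Insig1 (-1.14), Lss (-0.80) and Srebf2 (-0.35). For peroxisomes and fatty acid oxidation it was 10 of 17 and 2 (11 and 2 adjusted over the list alone; camera, adjusted p = 0.0616), with Ppara (-1.14) and Cpt1a (-0.86) lower and Pparg (1.58) and Pdk4 (1.41) higher.

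Neuroendocrine genes were higher. Of 17 measured members, 14 rose, 1 fell and 2 did not pass (14 and 1 adjusted over the list alone), and the median was 2.68 (camera, adjusted p = 2.91e-22; adjusted p = 0.0531 with an estimated correlation). The median was 2.73 among low-Y and 2.23 among high-Y libraries, and 2.74 with the mesenchymal covariate. The transcription factor gene Insm1 rose from 2.97 ± 1.29 to 48.4 ± 4.30 CPM (4.03, SE 0.17). The peptide gene Calca rose from 11.03 ± 5.42 to 366 ± 33.8 CPM (5.06, SE 0.23), as did Chga (3.24), the prohormone convertase gene Pcsk1 (3.70) and Nov (2.73). Scg2 (0.50) and Uchl1 (-0.24) did not pass, and the member that fell was Piezo2 (-1.11), named after its value was seen. The Notch ligand genes Dll3 (3.59) and Dll1 (1.64) rose, Nrarp (-0.93) fell and Hes1 (0.15) did not pass in a Notch list of 4 higher and 2 lower among 14 (4 and 2 adjusted over the list alone; camera, adjusted p = 0.322).

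Some gastric and intestinal markers were higher. Only 5 of 26 list members passed the filter on low counts, of which 4 rose and Agr2 (1.27) did not pass (5 and 0 adjusted over the list alone). The median was 2.90 (camera, adjusted p = 1.31e-04; adjusted p = 0.104 with an estimated correlation). Genes near 0 in Control, such as Tff3 and Gkn2, pass that filter only where the knockout is higher: without a filter the list had 24 members, a median of 0.31 and no call (camera, adjusted p = 0.119, the highest over camera's alternatives; the lowest was 3.12e-05). Muc5ac, a gastric and airway mucin, rose from 2.46 ± 1.04 to 18.5 ± 1.5 CPM (2.90), and Sox21 (2.22) and Gkn2 (3.47) rose. Tff3 had 1 count over the Control libraries and 123 over the knockout libraries, a ratio of 137 (95% counting interval 24.1 to 5445).

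Airway markers moved apart. In the secretory list 5 of 18 rose and 5 fell (5 and 5 adjusted over the list alone; camera, adjusted p = 0.0820): Sox2 (1.03), Fmo2 (1.78) and Upk3a rose and Hp (-1.79) fell, while Scgb3a2 (-0.17) and Muc5b (1.17) did not pass. Of 24 ciliated genes, 2 rose and 1 fell (0 and 0 adjusted over the list alone; camera, adjusted p = 0.803), with Ccno (0.25) and Mcidas (0.29) higher, Ccdc113 (-0.56) lower, and Foxj1 at 0.22, not called; these 3 calls were lost without some single libraries. In the basal list 3 of 9 rose, Trp63 (2.58), Krt14 (4.64) and Krt15 (1.17), and Pdpn (-0.61) fell (5 and 2 adjusted over the list alone; camera, adjusted p = 0.213). Krt5 had a log2 fold change of 1.88 and did not pass (edgeR, adjusted p = 0.0573).

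Of 32 lung epithelial transcription factors, 17 fell and 7 rose (17 and 7 adjusted over the list alone), with a median of -0.25 (camera, adjusted p = 3.53e-04; adjusted p = 0.117 with an estimated correlation). Irx1 (-1.47), Elf5 (-1.61) and Irx2 (-1.06) fell. Among 19 distal tip progenitor genes 8 fell and 5 rose (8 and 5 adjusted over the list alone), with a median of -0.24 (camera, adjusted p = 0.0193; adjusted p = 0.330 with an estimated correlation); Bmp4 (-1.80), Clu (-2.12) and Cpm (-0.83) fell. The tip list was not called with library-size scaling alone (median -0.13), with limma-voom (-0.24; -0.23 with library weights) or among high-Y libraries (-0.050), and its median was -0.044 without Control libraries 5 and 6.

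Wnt targets fell in 9 of 15 cases and rose in 3 (9 and 3 adjusted over the list alone), with a median of -0.46 (camera, adjusted p = 0.00303; adjusted p = 0.136 with an estimated correlation), among them Sp5 (-1.40) and Lgr5 (-2.31). In the TGF-beta and BMP list 12 of 18 fell and 4 rose (12 and 4 adjusted over the list alone), with a median of -0.50 (camera, adjusted p = 0.00303; adjusted p = 0.136 with an estimated correlation). Pmepa1 (-1.19) and Id2 (-0.57) fell. In lung ion and fluid transport 8 of 15 fell and 3 rose (9 and 3 adjusted over the list alone), with a median of -0.44 (camera, adjusted p = 0.00511; adjusted p = 0.330 with an estimated correlation). The chloride channel gene Cftr (-1.69), the anion transporter Slc26a9 (-2.22) and the sodium pump subunit Atp1b1 (-1.21) fell. This list was not called with limma-voom (median -0.42; -0.46 with library weights), and its median was -0.21 with the mesenchymal covariate and -0.27 among low-Y libraries.

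Antigen presentation genes fell in 13 of 14 cases (13 adjusted over the list alone), with a median of -0.97 (camera, adjusted p = 0.00106; adjusted p = 0.239 with an estimated correlation). Cd74, the class II invariant chain, fell from 59.7 ± 7.69 to 9.52 ± 2.31 CPM (-2.65, SE 0.14; chromosome 18, 60803848 to 60812652). Its regulator Ciita (-1.59) and the proteasome gene Psmb8 (-1.18) fell, while B2m rose from 44.1 ± 4.30 to 93.6 ± 9.53 CPM. In the extracellular matrix and axon guidance list 12 of 25 rose and 4 fell (12 and 6 adjusted over the list alone), with a median of 0.33 (camera, adjusted p = 0.0193; adjusted p = 0.330 with an estimated correlation). Ntn1 (1.41), Ntn4 (1.67) and Sema3f (1.01) rose and Sema3b (-1.72) fell. The list of mesenchymal markers was not called. Their mean log2 CPM was higher on average in knockout (4.57 to 5.33) than in Control libraries (3.87 to 4.76), with overlapping ranges. With the mesenchymal covariate the median of the matrix and axon guidance list was 0.056.

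Markers of other cell types that the selection could carry over were also higher in part. Mesothelial genes rose in 7 of 8 cases (7 adjusted over the list alone), with a median of 1.03 (camera, adjusted p = 0.00489; adjusted p = 0.330 with an estimated correlation), among them Upk1b (2.80), Aldh1a2 (2.12) and Msln (1.05). Mesenchymal genes rose in 9 of 19 cases (9 adjusted over the list alone; median 0.49; camera, adjusted p = 0.0794), among them Col3a1 (0.70), Ogn (0.92) and Postn (1.22). Col3a1, Ogn and Postn lost their calls under 3, 3 and 2 of 26 alternatives. The mesenchymal list was called under some alternatives, such as no filter on low counts (median 0.54), limma-voom (0.53) and leaving out Control libraries 5 and 6 (0.59). Immune genes rose in 8 of 14 cases (11 adjusted over the list alone; median 1.31; camera, adjusted p = 0.0820), with S100a9 at 3.90 and S100a8 at 3.91, and Lcp1 fell (-1.11). Endothelial genes rose in 6 of 12 cases (7 adjusted over the list alone; camera, adjusted p = 0.270), with Pecam1 at 1.07, and Kdr fell (-1.23). In Control, Msln (208 CPM), Lcp1 (303) and Kdr (58.1) stood far above Upk1b (6.24), S100a9 (1.29) and Pecam1 (5.28) of the same lists. Whether transcripts of these lists came from carried-over cells was not tested. Of 20 pan-epithelial genes 9 fell and 2 rose (9 and 2 adjusted over the list alone; median -0.15; camera, adjusted p = 0.117), with Elf3 (-1.05) and Cldn3 (-0.78) lower. With the mesenchymal level as a covariate the calls were 1720 higher and 1728 lower by edgeR.

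Of the 31 lists tested, 12 were called by camera with the preset correlation, 4 higher and 8 lower, and 0 with an estimated correlation; fry, which asks only whether a list moves on balance one way, called 23.

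**Figure D3:**
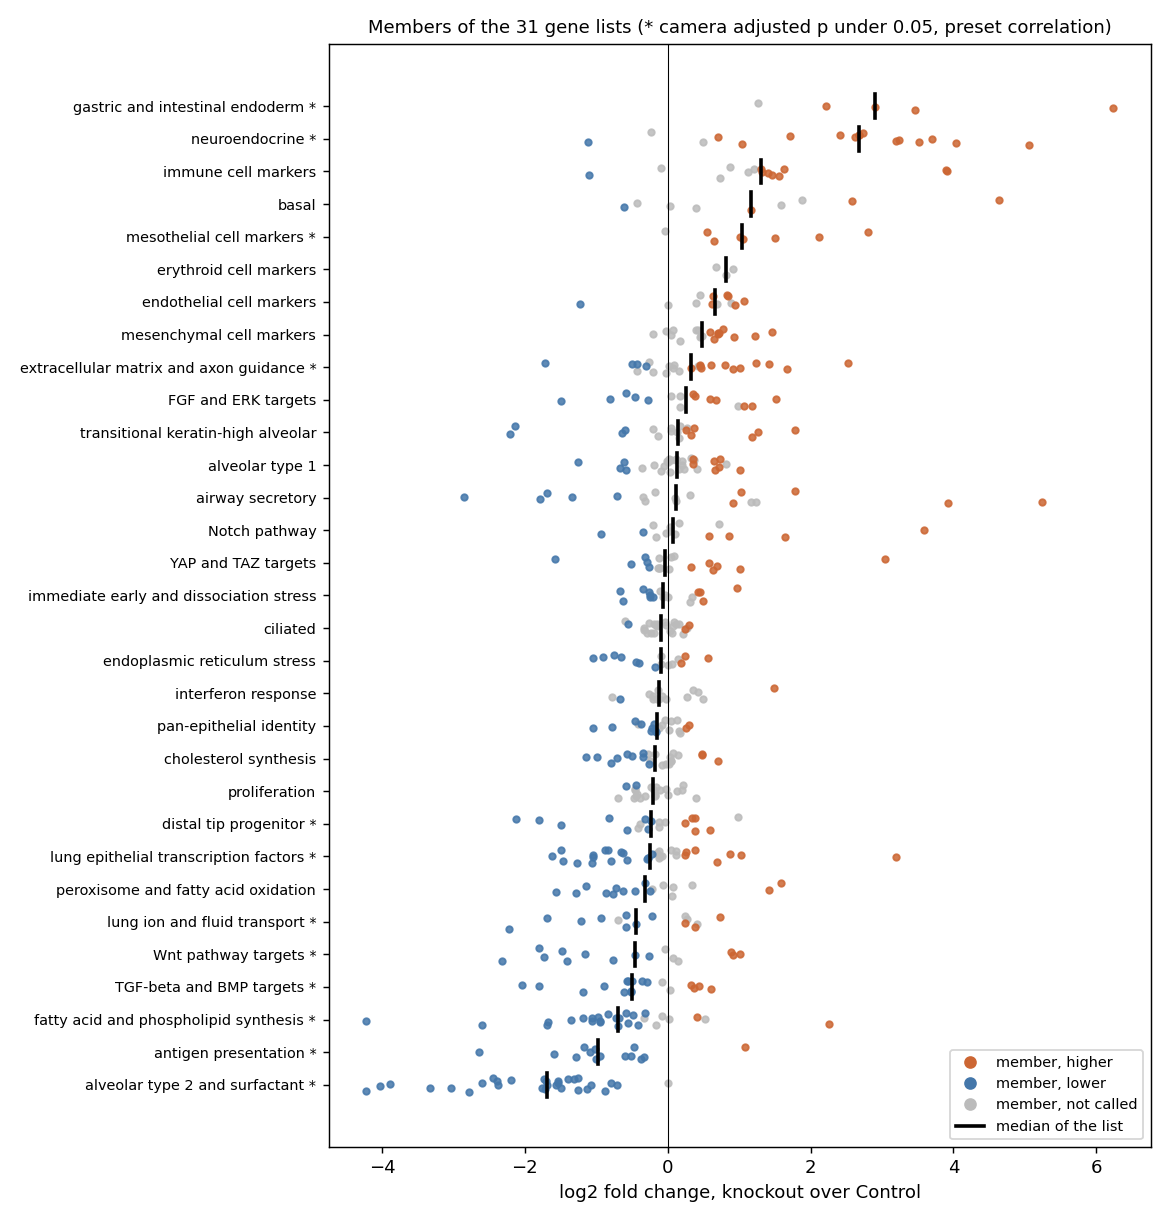
Log2 fold change, knockout over Control (horizontal), of each measured member of the 31 lists (rows, ordered by median); points are genes, coloured by whether edgeR called them, and bars are medians. The type 2 list lies lowest (median -1.69) and the gastric and neuroendocrine lists highest (2.90 and 2.68), the former over the 5 of 26 members that passed the filter; a star marks lists called by camera with the preset correlation.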

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

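The tests of alveolar type 1 markers, of exchanged libraries and of the deleted exons were chosen after the results they bear on were seen; the others were written before.

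The number of changed genes was set against other groupings of the same libraries. Among 100 random splits into groups of 5 and 6, the real one included, 1 gave as many calls as the real 5973, namely the real one. So many calls are therefore rare under random grouping. The splits cannot tell genotype from another difference between the same groups. The highest other split gave 4227 calls; its group of 5 held 0 knockout libraries, so it nearly follows genotype. The uneven share of libraries with Y-linked transcripts was tested too: over called autosomal genes, log2 fold changes among low-Y libraries followed those of all libraries with a slope of 1.01, although these fits share libraries. The genes were also chosen in the fit of all libraries, so the slope alone decides little. The 3753 calls among low-Y libraries alone argue against Y-linked level as the whole cause, and the genotype stays open.

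The lower alveolar type 2 genes were weighed against dilution by non-epithelial cells and against lungs of lower maturity. Dilution by non-epithelial cells would lower pan-epithelial genes alike. Their median was -0.146, against -1.69 for type 2 genes, which argues against such dilution as the whole cause. These values do not bear on a change in the mix of epithelial cell types, which was not tested. Lower maturity would lower type 1 genes too; their median was 0.136, over members that went both ways and not called, so it cannot be told apart from an effect of the genotype. Loss of both targeted genes, the difference the design names, stays open beside it.

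Mecom was higher and Prdm16 only slightly lower in the knockout. Exchanged libraries would leave a library of each group matching the other group best, and 0 libraries did. Reads from exons outside the deleted part may keep the counts up: the whole-gene Prdm16 log2 fold change was -0.285, but counts per exon were not analysed here, so this cannot be told apart from incomplete deletion. A rise in Mecom transcription as an effect of the knockout was not tested.

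In 370 tests of a gene or list within a group, 20 had a library far from the others, where chance gives about 18.5 (1 in 20); Control library 4 held 5 of them and knockout library 4 held 4. In Control library 4 the values were 0.520 CPM for Prss32 (others up to 0.160), 58.4 for Sprr1a (others up to 38.7), 928 for Hp (up to 575), 1108 for Foxj1 (up to 866) and 77.7 for Nrarp (up to 62.0). In Control library 2, Car10 was at 0.138 CPM (others 0) and Postn at 0.553 (others from 2.08). Control library 5 had Tff3 at 0.138 CPM (others 0), and Control library 3 had the lung transcription factor list at a mean log2 CPM of 7.76 (others up to 7.65).

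In knockout library 4, Slc8a3 was at 110.5 CPM (others up to 88.8), Pcsk1 at 39.0 (others from 47.8) and Uchl1 at 3.99 (others from 5.70), and the FGF and ERK list had a mean log2 CPM of 6.41 (others up to 6.32). Knockout library 1 had Ros1 at 0.796 CPM (others from 1.15) and Ntn4 at 30.8 (others up to 27.7). Knockout library 2 had Mcidas at 77.3 CPM (others from 93.2), Cftr at 43.9 (others up to 39.5) and Ifi44 at 9.85 (others up to 8.35). Knockout library 3 had Scgb3a2 at 204 CPM (others up to 163) and knockout library 5 had Pla2g2f at 6.79 (others up to 5.53).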

How the results depend on the processing

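Leaving out Control libraries 5 and 6 and fitting the low-Y and high-Y libraries apart were chosen after seeing the data; the other settings were fixed before. Of 151 named genes besides Prdm16 and Mecom, 111 kept their direction and their side of the threshold under all 26 settings run for genes, 25 lost and 7 gained a call under some setting, and 11, none of them called, changed sign under some setting. Mecom was called under each of them. Camera was not run with DESeq2, which called 2905 genes higher and 3077 lower. Small changes can be missed with these libraries. In simulated data of the same depth, spread and group sizes, 60% of genes changed 1.5-fold were called. Only 225 simulated genes were changed, however, while 42.9% of genes were called in the real data. With fewer changed genes the adjusted threshold is stricter, so 60% may understate the share found in the real data. Except where stated, the cause of a change was not tested.

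The Prdm16 log2 fold change was -0.176 with library size only, -0.200 with the mesenchymal covariate and -0.178 among high-Y libraries, not called in each. The calls were 1720 higher and 1728 lower with the mesenchymal covariate, which is itself higher in the knockout, 1932 and 1821 among low-Y and 869 and 933 among high-Y libraries, where fewer libraries were tested. The lists called were 0 with an estimated correlation, where the type 2 median of -1.69 has an adjusted p of 0.104 by camera, and 23 with fry. The type 1 median was -0.00392 without Control libraries 5 and 6.

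The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.0643 to 0.260, over 0.1 in 1 of 5 pairs, and 1 of the 5 knockout libraries matched its own number best. With the replicate number as a block the calls were 3079 higher and 3118 lower, the Lyz2 log2 fold change was -0.187, the Gprc5a log2 fold change -0.0527 and the Mki67 log2 fold change 0.0130.

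The Timp3 log2 fold change was 0.112 with library size only, 0.0566 with upper-quartile factors, 0.00937 without a filter, 0.0189 with limma-voom, 0.0385 with the Y-linked covariate, 0.30 with the mesenchymal covariate and 0.0639 among low-Y libraries. The Lyz2 log2 fold change was -0.000742 with at least 1 CPM in 5 libraries and the Gprc5a log2 fold change -0.00251 with library weights. Leaving out each library in turn gave -0.0985 to 0.0589 for Timp3, -0.246 to 0.244 for Lyz2 and -0.0603 to 0.0594 for Gprc5a. The Epcam log2 fold change was -0.00920 and the Scgb3a2 log2 fold change 0.129 with the mesenchymal covariate, and at -0.00410 and 0.229 among low-Y libraries. Without Control libraries 5 and 6, these were -0.342 for Lyz2 and -0.144 for Gprc5a, the Uchl1 log2 fold change was 0.158, the Hopx log2 fold change -0.0264 and the Mki67 log2 fold change 0.185. Among high-Y libraries, the Muc5b log2 fold change was -0.478, the Krt5 log2 fold change -1.13 and the Agr2 log2 fold change -0.905. Single libraries decided some calls of ciliated genes: Ccdc113 lost its call without Control library 5 or knockout library 2, Ccno without Control library 3 or knockout library 3 or 5, and Mcidas without Control library 3 or knockout library 1 or 5.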

Other observations

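Several lists held genes that moved in opposite directions with no call for the list. In the transitional keratin-high alveolar list 6 of 18 rose and 4 fell (7 and 4 adjusted over the list alone; camera, adjusted p = 0.803): the EGF receptor ligand genes Areg (-2.14) and Ereg (-2.20) fell, Plaur (1.78) and Sprr1a (1.26) rose, and Krt19 (0.17) did not pass. Of 16 FGF and ERK targets 7 rose and 5 fell (7 and 5 adjusted over the list alone; camera, adjusted p = 0.803), with Dusp5 (1.07) and Myc (0.68) higher and Phlda1 (-0.81) lower. Of 18 YAP and TAZ targets 6 rose and 5 fell (6 and 5 adjusted over the list alone; camera, adjusted p = 0.527): Ankrd1 (3.04) and Axl (1.01) rose, and Cyr61 was at -0.12, not called; the list median was -0.044 while its mean (0.17) and camera's direction were higher. In endoplasmic reticulum stress 7 of 15 fell and 3 rose (7 and 3 adjusted over the list alone; camera, adjusted p = 0.270), with Dnajb9 (-1.05), Sesn2 (-0.90) and Trib3 (-0.75) lower and Sdf2l1 (0.57) higher.

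Immediate early genes, which dissociation can induce, fell in 7 of 17 cases and rose in 4 (7 and 5 adjusted over the list alone; camera, adjusted p = 0.929): Fosb (0.98) and Fos (0.46) rose, and Klf6 (-0.63) and Zfp36 (-0.66) fell; the median was -0.068, while the mean (0.011) and camera's direction were higher. Of 22 proliferation genes, Pcna (-0.45) and Rrm2 (-0.59) fell (1 adjusted over the list alone; camera, adjusted p = 0.628) and Mki67 was at -0.47, not called. The Rrm2 log2 fold change (edgeR, adjusted p = 0.0462) lost its call under 16 of 26 alternatives, with adjusted p from 0.0114 to 0.209. Rrm2 was at 38.0 and 50.1 CPM in Control libraries 5 and 6, 18.1 to 28.8 in the other Control and 16.5 to 23.8 in the knockout libraries, and without Control libraries 5 and 6 its value was -0.23 (edgeR, adjusted p = 0.187); it was also not called without Control library 4, 5 or 6 or without any one knockout library. Of 15 interferon response genes, Ifi44 (1.49) rose and Ifit2 (-0.67) fell (1 and 1 adjusted over the list alone; camera, adjusted p = 0.803); the median was -0.13 and the mean 0.027. Of 3 measured erythroid genes 0 were called (0 adjusted over the list alone; camera, adjusted p = 0.786).

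Count levels of some common transcripts, named after their values were seen, were low for poly(A) RNA; the tests below were chosen before their results were seen. Gapdh had a mean of 131 counts per library, Eno1 had 2 counts over all 11 libraries and Hba-a1 and Hbb-bs had 0. Counts per kilobase of 71 ribosomal protein genes had a median percentile of 55.1 among 13708 genes, and the pseudogene Rpl14-ps1 had a mean of 7590 counts against 856 for Rpl14. Reads lost over exon junctions, as a hypothesis, would give higher counts per kilobase to ribosomal protein genes with a long exon. Across 77 ribosomal protein genes, Spearman's rho was -0.148 (permutation p = 0.199, two-sided). Of the 20 genes with the most counts per kilobase, however, 6 had at least 90% of their length in a single exon. Of all genes ranked, 5.19% did. That difference goes with lost junction reads but was not tested. Reads lost to pseudogenes and copies, as another hypothesis, would give lower counts to genes sharing more sequence, and rho was 0.152 (permutation p = 0.187, two-sided). Neither correlation lies in the direction its hypothesis needs. Both are across genes, which are not independent replicates. Counts were divided by the length of all exons of a gene. The longest exon and the share of sequence in other genes were those of its longest transcript. A long transcript can thus lower counts per kilobase and the shared part while lengthening the exon. These correlations therefore decide neither hypothesis.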
